A study of Mus musculus with 4 samples.

How the data were processed

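RNA of NIH 3T3 cells, a mouse fibroblast line, was compared on 4 two-colour oligonucleotide arrays. Each array set Cy5-labelled RNA of cells with a knockdown construct against Cy3-labelled RNA of cells with the empty pU6-m3 vector. The constructs target Selt, now named Selenot, which encodes selenoprotein T. siSelT-1 covers nucleotides 205 to 224 of its mRNA and siSelT-5 nucleotides 971 to 989, and each was measured on 2 arrays. Per the labels, the replicates used RNA of different cultures taken at different times, and the medium held 150 µg/ml hygromycin, 10% serum and 100 nM selenite. RNA was extracted with Trizol and copied with oligo-dT primers before dye coupling.

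The deposited values are log ratios of the channels of each array, here read as log2. The labels do not state the base, background correction, normalization or filter. Read as log10, the highest value, 4.69, would take nearly the whole range of a 16-bit scanner, so log2 is more plausible, but base 10 is not excluded and every fold rests on this reading. The ratio was read as knockdown over vector, from the order in the sample titles and from the dye labels; a reversed ratio would turn every direction given here. The knockdown RNA carried the same dye on all 4 arrays, so a gene-specific dye effect is not cancelled against vector, but it cancels in siSelT-1 minus siSelT-5. Whether the arrays shared vector RNA is not stated, and the spread of the vector cultures enters no test. No probe carried the name of the targeted gene, so its level was not analysed here and the labels were not checked on it.

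The table held 22534 probes, of which 18129 carried a single gene name, 140 several and 4265 none. Names were updated through Entrez identifiers with the GRCm38.p6 annotation, which matched 18041 probes, changed 0 symbols and otherwise gave only the order of genes along chromosomes. A gene was tested where it had a probe of a single name with a value on all 4 arrays, and it was represented by the mean of such probes, since the table gives no signal by which to choose a probe. This left 4754 genes, 3796 with 1 probe and 958 with more. The plan had adjusted over all probes; the restriction to named genes was made afterwards, and the fit with unnamed probes is among the alternatives.

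Ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with statmod 1.5.0) as 2 group means with 2 residual degrees of freedom. The contrasts were the mean of both constructs against 0, each construct against 0, and siSelT-1 minus siSelT-5. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 4754 genes, two-sided. The median ratio of the probes shared by all arrays lay above 0, so counts and list calls are also given with every array centred on the median of those shared probes. The precision is limited by the number of arrays.

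Comparisons, the rule for named genes, 28 gene lists and most alternatives were fixed before the data were examined. Named genes were the 12 highest and 12 lowest that passed with the same sign on all 4 arrays, the 6 highest and 6 lowest for each construct and for the difference, every measured selenoprotein, and up to 4 members of each other list with the smallest unadjusted p. For the difference, places left open went to genes in the order of unadjusted p, said not to have passed. Other members named were chosen after their values were seen. The 20 lists with 5 or more measured genes were tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over lists. fry was run as well. It does not compare a list with other genes, and it is not reported further. The 8 smaller lists are given as values. Some lists share genes, such as Prdx1 in the thioredoxin fold and the NRF2 lists and Ccn2 in the matrix and the immediate early lists.

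Agreement of the constructs was set beside 100 simulations of unchanged groups that share 1 vector culture. The pipeline was tested on simulated data with 200 changed genes in 20 runs. For both constructs together it recovered 85.2% of changes of 0.5 log2 and 99.6% of changes of 1. For siSelT-1 minus siSelT-5 it recovered 6.12% and 77.9%. False calls were 6.84% to 8.00% of calls, and 0 lists per run were called by camera with none changed. The simulated genes were independent and had the same spread for both constructs. These rates therefore do not cover lists of correlated genes or constructs of unequal spread.

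The alternatives were centring, a common spread, a looser filter on missing values, single probes, unnamed probes, genes with several probes, robust eBayes, array weights, a replicate block, each array left out, other thresholds and other sets of arrays. limma's own scale method does not take log ratios with these values, so arrays were centred and divided by their median absolute deviation directly. For the targeted gene there was no value to recompute under any alternative, so none was run. Bootstrap intervals are 95% intervals from 2000 draws, and p-values of gene order come from 199 random orders.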

Results

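Expression was measured as the ratio of knockdown to vector RNA in NIH 3T3 mouse fibroblasts, with 2 arrays for construct siSelT-1 and 2 for siSelT-5. The siSelT-1 arrays gave a value for 7689 and 9232 of 22534 probes, and the siSelT-5 arrays for 20268 and 18361. The medians of all values were 0.18 and 0.06 log2 on the siSelT-1 arrays and -0.22 and -0.19 on the siSelT-5 arrays. On the 7038 probes with a value on all 4 arrays they were 0.19, 0.09, 0.43 and 0.36. The mean shift of these shared probes was 0.14 for siSelT-1 and 0.39 for siSelT-5, and ratios called centred below are taken from it. Across 4754 genes, which are not independent replicates, Pearson's r was 0.844 between the siSelT-1 arrays, 0.660 between the siSelT-5 arrays and 0.456 to 0.516 between arrays of different constructs.

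Both constructs together against vector ask whether the mean ratio over the 2 constructs differed from 0. A gene moved by 1 construct alone can pass. The carbonyl reductase gene Cbr3 (Entrez Gene 109857) stood highest, at a log2 ratio of 2.67 ± 0.64 (SD, n = 4), or 6.36-fold. Other genes that rose included Gstm1, a glutathione S-transferase, at 1.39 ± 0.15, the transcription factor Ets2 at 1.41 ± 0.26, the nucleosome-binding protein gene Hmgn1 at 1.38 ± 0.12, and Rpph1, the RNA component of ribonuclease P, at 1.57 ± 0.24. Usp37 (1.51 ± 0.36), Slc9a3r2 (1.48 ± 1.05), Cyp7a1 (1.48 ± 0.25), Bahcc1 (1.46 ± 0.32), Dop1b (1.43 ± 0.57), the kinesin gene Kif17 (1.37 ± 0.20) and Asphd2 (1.35 ± 0.48) rose too. The matrix genes Thbs1, for thrombospondin 1, and Eln, for elastin, fell, to -1.43 ± 0.47 and -1.14 ± 0.68. Ccn2, the connective tissue growth factor, stood at -1.30 ± 0.80, the inhibitory G protein subunit Gnai1 at -1.29 ± 0.64, the stress-induced Nupr1 at -1.11 ± 0.09 and the calcium channel subunit Cacnb2 at -1.10 ± 0.80. Prpf38b (-1.22 ± 1.06), 1700001F09Rik (-1.22 ± 0.53), Pogk (-1.22 ± 0.90), Rtca (-1.20 ± 0.10), Hsd17b4 (-1.13 ± 0.70) and Uvssa (-1.05 ± 0.84) completed the lowest genes. All 24 passed as deposited (adjusted p 0.00161 to 0.0121) and centred (0.00413 to 0.0136), with the same sign on 4 of 4 arrays as the rule for naming required. For siSelT-1 alone Prpf38b, Pogk, Uvssa, Hsd17b4 and Ccn2 did not pass (limma, adjusted p 0.105 to 0.364). For siSelT-5 alone Slc9a3r2 (0.0708) and Cacnb2 (0.0518) did not. For 14 of the 24 genes, Cbr3 included, the table held a single probe. Probes of a gene agreed loosely in these data. Among 945 genes with at least 2 probes on all arrays, those with 9 or more probes left out, 2 probes of a gene correlated at a Pearson's r of 0.317. These are means of the 4 arrays, and 67.8% of the pairs had the same sign.

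Over all 4754 genes, 2554 passed, 2172 higher and 382 lower, so that 85.0% were higher. Of these, 106 moved at least 2-fold, 90 up and 16 down. After centring, 2015 passed, 976 higher and 1039 lower (48.4% higher), of which 75 moved at least 2-fold, 16 up and 59 down. On both scales 976 higher and 382 lower genes passed. As deposited, 510 genes passed for each construct alone, 499 of them in the same direction, against 350 that independent lists would share. Without siSelT-1 replicate 1 limma called 0 genes, with 1846 at an unadjusted p under 0.05, and without siSelT-1 replicate 2 it called 873. Of the 24 named genes, 10 had further probes, dimmer or measured on fewer arrays. Among the 6 higher ones, 4 had further probes whose mean siSelT-5 ratios had the opposite sign: Usp37, Slc9a3r2, Bahcc1 and Kif17. Among the 4 lower ones 0 had. The further probe of Thbs1 nonetheless averaged -0.06 with siSelT-5, against -1.76 for the tested probe. That of Gstm1 stood at 0.38 on siSelT-5 replicate 1, its only siSelT-5 value, against 1.39 for the tested probe.

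**Figure D1:**
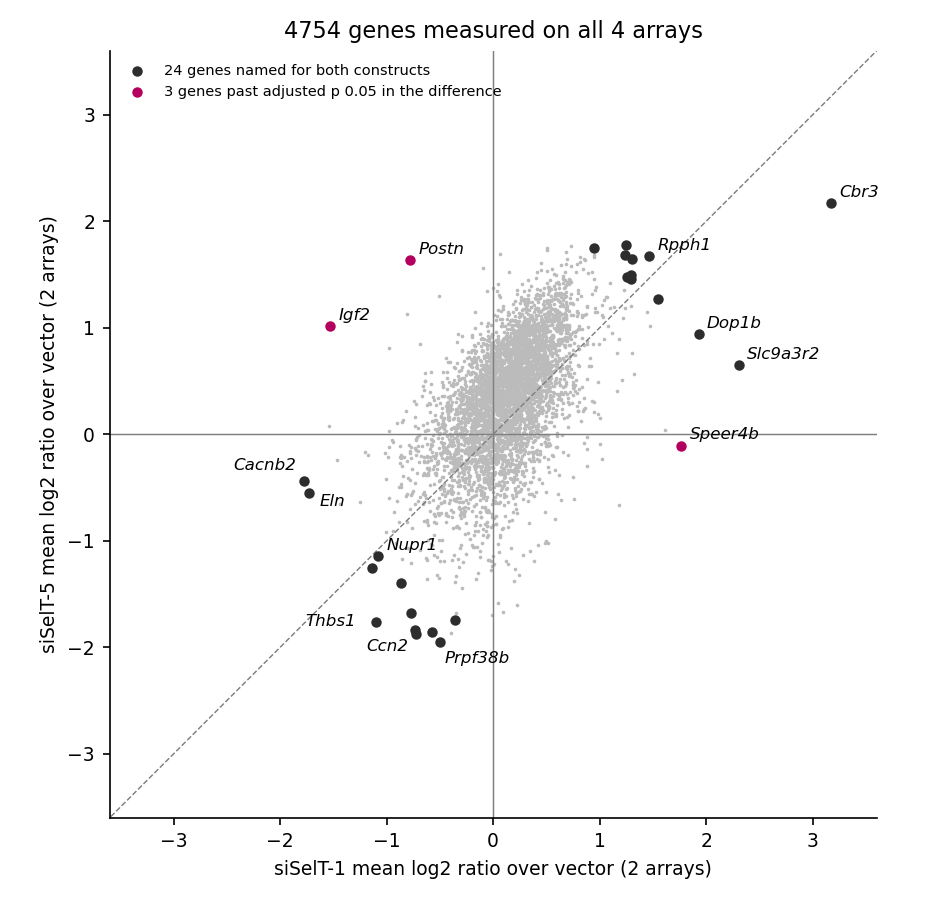
Mean log2 ratio over vector of 4754 genes for siSelT-1 (x axis) and siSelT-5 (y axis), 2 arrays each, with 24 genes named for both constructs in black and the 3 genes whose difference passed in magenta; the dashed line marks equal ratios. Cbr3 lies at 3.17 and 2.17, while Igf2 and Postn lie below 0 for siSelT-1 and above 0 for siSelT-5.

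Selenoprotein transcripts mostly stood above vector: of 24 genes 14 were measured, and 9 rose and 1 fell over all genes, with 11 and 1 adjusted over the list alone. Selenow rose to 1.18 ± 0.22 (SD, n = 4), the deiodinase gene Dio2 to 1.05 ± 0.18, Selenok to 0.82 ± 0.18 and the glutathione peroxidase gene Gpx4 to 0.75 ± 0.35. Selenop, the secreted carrier of selenium in plasma, fell to -0.43 ± 0.26. These 5 also passed after centring. Selenoh (0.64), Selenom (0.56), Msrb1 (0.44), Gpx1 (0.35) and Txnrd3 (0.25) passed as deposited only, and Txnrd3 turned to -0.01 after centring. Txnrd1 (0.35), Selenof (0.22), Selenos (0.03) and Selenon (-0.11) did not pass. As a list they were not called against other genes (camera, median 0.39, adjusted p = 0.401). siSelT-1 alone gave 3 higher and 1 lower, and siSelT-5 8 higher and 0 lower in limma, with 6 members not passed.

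**Figure D2:**
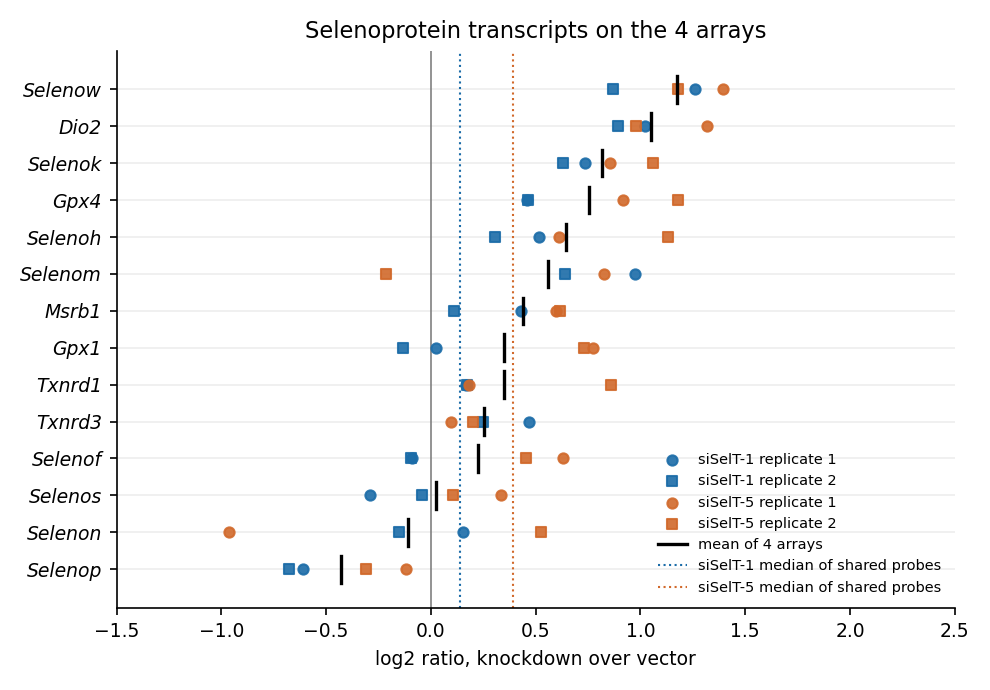
Log2 ratio over vector (x axis) of 14 selenoprotein genes on each of the 4 arrays, with bars at the means and dotted lines at the construct medians of shared probes. Selenow, Dio2, Selenok and Gpx4 lie right of both dotted lines on every array, Selenop lies left of 0 on every array, and Txnrd3 turns from 0.25 to -0.01 once arrays are centred.

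Genes of glutathione conjugation and other NRF2 targets included some of the highest ratios. Of 27 measured, 14 rose and 2 fell, over all genes and adjusted over the list alone. After centring 14 rose and 5 fell. Beside Cbr3 and Gstm1, the heme oxygenase gene Hmox1 rose to 1.15 ± 0.16 (SD, n = 4) and Aldh3a1 to 1.07 ± 0.13. Cbr3 also belongs to the raised run of neighbours on chromosome 16 given below. The transporter gene Abcc1 fell to -0.69 ± 0.19, and Nfe2l2, which encodes NRF2 itself, to -0.51 ± 0.35. Nqo1, a standard NRF2 target, stood at -0.04 and did not pass. The list was not called (median 0.51, adjusted p = 0.363). Of 25 thioredoxin fold and antioxidant genes, 18 rose and 0 fell over all genes, with 18 and 1 adjusted over the list alone and 12 and 2 after centring. Examples were the superoxide dismutase gene Sod1 at 1.18 ± 0.17, the disulfide isomerase genes Pdia4 and P4hb at 1.04 ± 0.52 and 0.89 ± 0.44, and Prdx1 at 0.93 ± 0.31. This list stood at a median of 0.57 and missed the threshold as deposited (adjusted p = 0.0702). It was called after centring (0.0216), with a common spread (0.0145) and with a single mean over the 4 arrays (0.0446), but not after centring with an estimated correlation (0.432).

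Ribosomal protein genes stood highest of the 20 lists tested, with a median of 0.86. Of 44 measured, 43 rose and 0 fell over all genes and adjusted over the list alone, and 37 and 0 after centring. Rps2 stood at 1.32 ± 0.43 (SD, n = 4), Rpl28 at 1.25 ± 0.46, Rps14 at 1.20 ± 0.42 and Rpl26 at 1.14 ± 0.53, while Rps15a, at -0.46, did not pass. Of 61 oxidative phosphorylation genes, 50 rose and 1 fell over all genes, 51 and 1 adjusted over the list alone and 33 and 3 after centring, with a median of 0.58. Atp5h reached 1.24 ± 0.51, Cox7c 1.17 ± 0.55, Ndufa3 1.08 ± 0.44 and Atp5j2 1.05 ± 0.58, and Ndufs1 fell to -0.32 ± 0.31. Both lists were called against other genes (camera, adjusted p = 1.22e-08 and 1.18e-05, and 5.75e-14 and 9.83e-08 after centring), though not with genes of several probes alone (adjusted p = 0.0831 and 0.177). The oxidative phosphorylation call was also lost with single probes (0.159). There a gene counts once per probe, so genes with many probes weigh more. Neither call held with the estimated correlation, at an adjusted p = 0.795 with an estimated correlation for each. Dimmer probes of these genes, with values on the siSelT-5 arrays and none on siSelT-1, stood at -0.18 against all dimmer probes (95% interval -0.23 to 0.16, 23 probes). They were 7 probes of 6 ribosomal protein genes and 16 probes of 9 oxidative phosphorylation genes. Probes of these lists with a value on a single siSelT-1 array stood 0.55 above all such probes of the siSelT-1 arrays (0.09 to 0.76, 34 probes of 22 genes). Both intervals resampled probes, not genes, and genes with 9 or more probes were kept.

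Immediate early and serum response genes stood below the other genes, with a median of -0.20. Of 16 measured, 3 rose and 6 fell over all genes, 3 and 7 adjusted over the list alone and 2 and 10 after centring. Beside Ccn2, the phosphatase genes Dusp6 and Dusp1 fell to -0.63 ± 0.24 and -0.43 ± 0.24 (SD, n = 4), and the zinc finger genes Klf6 and Egr1 to -0.60 ± 0.10 and -0.51 ± 0.52. Phlda1 rose to 0.58 ± 0.44 and Fosl2 to 0.52 ± 0.22. The call was at an adjusted p = 0.000467, or 0.00635 after centring, and at an adjusted p = 0.795 with an estimated correlation.

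Extracellular matrix genes moved both ways: of 47 measured, 15 rose and 9 fell as deposited and 9 and 13 after centring. Eln, Thbs1 and Ccn2 stood lowest, Tnc, for tenascin C, fell to -0.69 ± 0.29 (SD, n = 4), and Col6a2 and the collagen chaperone gene Serpinh1 rose to 0.87 ± 0.44 and 0.70 ± 0.33. Of 12 fibroblast markers, 4 rose and 3 fell, with Pdgfra at 0.88 ± 0.28, Vim at 0.57 ± 0.29 and Fn1, for fibronectin, at -0.61 ± 0.32, but 2 rose and 6 fell after centring. Medians were 0.15 and 0.07 as deposited and -0.12 and -0.20 centred, and neither list was called (adjusted p = 0.342 and 0.401). Of 20 matrix protease and inhibitor genes, 11 rose and 2 fell, among them Adamts1 at 0.88, Serpinf1 at 0.81 and Timp2 at 0.63 (median 0.31, adjusted p = 0.567), with 8 and 4 after centring. Of 49 focal adhesion and actin genes, 20 rose and 3 fell, led by Rac1 at 1.02 and Cfl2 at 0.78, but 9 and 13 after centring, where the median turned from 0.19 to -0.07 (adjusted p = 0.853). Of 18 cadherin and cell adhesion genes, 10 rose and 0 fell, led by the junction protein gene Jup at 1.29 ± 0.16, with Ctnna1 at 0.82 and Sdc1 at 0.67 (median 0.34, adjusted p = 0.670), but 5 and 4 after centring. Counts as deposited in this paragraph were the same over all genes and adjusted over the list alone.

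No other list was called for both constructs as deposited, and after centring the thioredoxin fold list alone was added. Of 27 calcium handling genes 15 rose and 3 fell, with Camk2b at 1.07 and Anxa4 at 0.87, but 6 and 7 after centring (median 0.44, adjusted p = 0.647). Of 20 TGF-beta and BMP genes 11 rose and 0 fell, with Id3 at 0.89 and Ltbp1 at 0.81, but 4 and 4 after centring (median 0.27, adjusted p = 0.987). Of 13 cell cycle genes 8 rose and 2 fell, with cyclin D1, Ccnd1, at 0.80 and the helicase gene Mcm2 at -0.92, and 4 and 2 after centring (median 0.41, adjusted p = 0.987). Of 15 p53 targets 10 rose and 1 fell, with the cell cycle inhibitor gene Cdkn1a at 0.87 and Gtse1 at 0.59, but 1 and 2 after centring (median 0.36, adjusted p = 0.567). Of 20 unfolded protein response genes 8 rose and 0 fell, with the chaperone gene Hspa5 at 0.75 and Atf4 at 0.69, and 6 and 2 after centring, where the median turned from 0.22 to -0.04 (adjusted p = 0.442). Of 18 glycolysis and hypoxia genes 11 rose and 1 fell, with Tpi1 at 0.77 and Vegfa at 0.67, and 6 and 4 after centring (median 0.43, adjusted p = 0.442). Of 17 chemokine and inflammatory genes 5 rose and 3 fell, with Il1r1 at -0.79, Il1a at -0.84 and Cxcl5 at 0.61, but 4 and 6 after centring, where the median turned from 0.04 to -0.23 (adjusted p = 0.342). Of 13 interferon response genes 4 rose and 2 fell, with Ifitm3 at 0.96, Ifi27 at 0.76 and H2-K1 at -0.82, and 2 and 2 after centring, where the median turned from 0.13 to -0.13 (adjusted p = 0.691). Of 5 cholesterol synthesis genes Hsd17b7 rose to 0.56 and Fdps fell to -0.55, also after centring (median -0.03, adjusted p = 0.442). Counts as deposited here too were the same adjusted over the list alone.

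The 8 lists too small for a test covered other cell types, integrins and the selenocysteine machinery. The endothelial markers Cd34 (0.72), Tie1 (0.72), Pecam1 (0.70) and Ramp2 (0.42) rose, as did the adipocyte markers Scd1 (0.71) and Lpl (0.64), the bone and cartilage markers Sox9 (0.62) and Bglap (0.61) and the muscle marker Des (0.44). Ramp2 and Des did not pass after centring. Mgp (-0.20) and the macrophage markers Lyz2 (-0.20) and Lyz1 (-0.16) did not pass as deposited but passed below the shift after centring. No epithelial marker was among the tested genes. Among integrins and related genes Itgb1 (0.39) and Itgb5 (0.33) rose and Itgbl1 (-0.53) fell, with Itga5 (0.15) not passed; after centring Itgbl1 alone passed. Of the selenocysteine machinery Eif4a3 (0.50) and Rpl30 (0.46) rose, Rpl30 as deposited only, and Trnau1ap (0.09) did not pass.

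**Figure D3:**
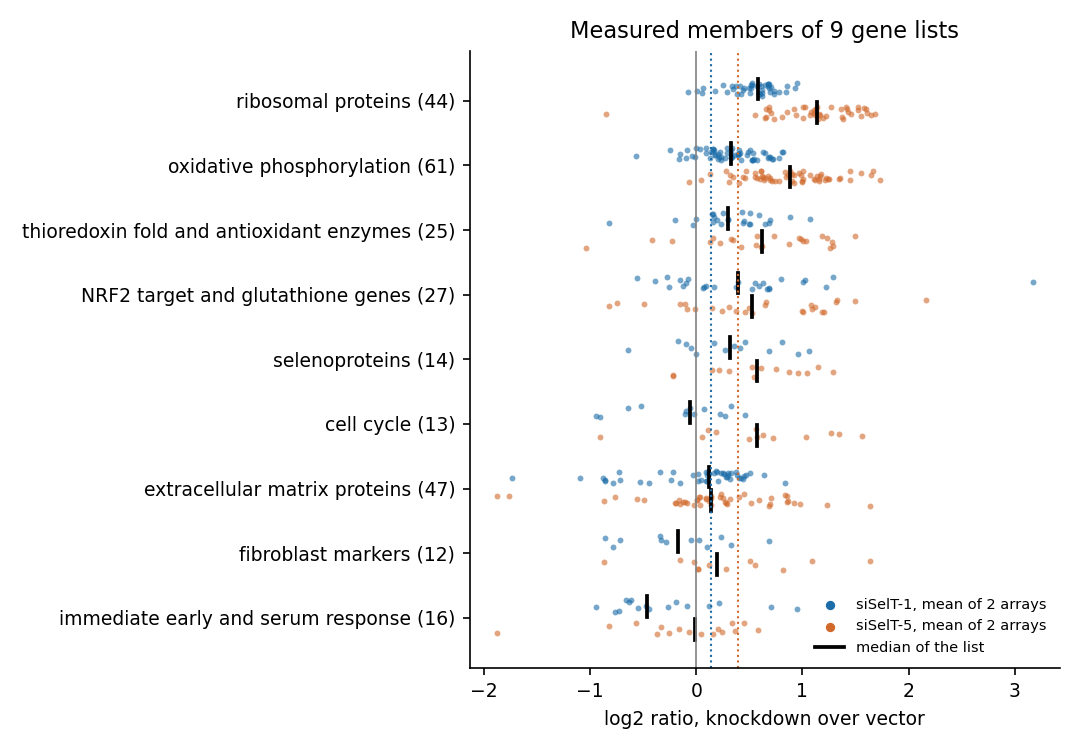
Log2 ratios over vector (x axis) of the measured members of 9 lists, as means of 2 arrays for siSelT-1 (blue) and siSelT-5 (orange), with black bars at list medians and dotted lines at each construct's median of shared probes. Ribosomal protein genes have medians of 0.58 and 1.13, and for both constructs together the medians of the matrix and fibroblast lists turn from 0.15 and 0.07 to -0.12 and -0.20 after centring.

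siSelT-1 against vector, the construct with the closer replicates (root mean square SD 0.164 against 0.349), asks what this construct alone changed. Cbr3 again stood highest, at 3.17 ± 0.02 (SD, n = 2), with Slc9a3r2 at 2.31 ± 0.54, Dop1b at 1.93, Speer4b at 1.77, Bptf at 1.62 and Ets2 at 1.54. The growth factor gene Igf2 fell to -1.53 ± 0.15, Eln to -1.73 ± 0.11, Cacnb2 to -1.77 ± 0.09 and Ewsr1 to -1.47 ± 0.08, and B230206H07Rik and Ttyh1 were among the 6 lowest as well. For Bptf, a further probe stood at -0.97 on siSelT-1 replicate 2, its only siSelT-1 value, against 1.87 for the tested probe on that array. Another Bptf probe had values on the siSelT-5 arrays alone, at -0.26 and -0.79. Of the fibroblast markers, Dcn, Postn and Col3a1 fell, to -0.86, -0.78 and -0.72, and Pdgfra rose to 0.68, so 1 rose and 3 fell over all genes and adjusted over the list alone (median -0.17). Immediate early genes stood at a median of -0.46, with 2 higher and 5 lower, or 2 and 8 adjusted over the list alone, and Egr1 at -0.94. Ribosomal protein genes (median 0.58; 23 higher, 36 adjusted over the list alone), oxidative phosphorylation genes (0.33; 15 higher and 1 lower, 23 and 1 adjusted over the list alone) and thioredoxin fold genes (0.30; 7 higher, 11 and 1 lower adjusted over the list alone) stood above other genes. After centring, fibroblast markers had 0 higher and 3 lower, immediate early genes 2 and 7, ribosomal 11 and 0, oxidative phosphorylation 6 and 1 and thioredoxin fold genes 3 and 0. The camera adjusted p was 0.0389 for fibroblast markers, 0.000496 for immediate early, 4.74e-09 for ribosomal, 0.00187 for oxidative phosphorylation and 0.0163 for thioredoxin fold genes, against an adjusted p = 0.757 with an estimated correlation for each. After centring these were 0.0433, 0.00406, 6.67e-11, 0.00206 and 0.0104, and the NRF2 list, which missed the threshold as deposited (0.0585), was called as higher (0.0262), but not with an estimated correlation (0.440). The fibroblast call was also lost with arrays centred on all values (adjusted p = 0.0526), with a common spread (0.0610) and with a value required on 1 array of each group (0.0584), where the median turned to 0.026. The oxidative phosphorylation call was lost with single probes (0.955), where a gene counts once per probe. With genes of several probes alone the ribosomal, oxidative phosphorylation, thioredoxin fold and fibroblast calls were lost (0.0627, 0.573, 0.915 and 0.145).

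For siSelT-1 650 genes passed, 490 higher and 160 lower (75.4% higher), and after centring 423, 182 higher and 241 lower (43.0%). The 12 named genes passed on both scales (adjusted p 0.00838 to 0.0296 as deposited). With the replicate number as a block 35 genes passed, 11 of the 12 named among them, and Bptf did not (0.0534). limma called 0 genes without siSelT-1 replicate 1 and 0 without siSelT-1 replicate 2, with 390 and 585 at an unadjusted p under 0.05, and 2089 without either siSelT-5 array.

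siSelT-5 against vector asks the same of the other construct, whose arrays varied more. Cbr3 stood at 2.17 ± 0.46 (SD, n = 2), Usp37 at 1.78 ± 0.30, the histone genes H2bc15 and H2bc13 at 1.77 ± 0.06 and 1.75 ± 0.12, Asphd2 at 1.74 ± 0.09 and Ndufa4, of the respiratory chain, at 1.73 ± 0.29. Prpf38b stood lowest, at -1.95 ± 1.13, followed by Ccn2 at -1.88 ± 0.75, Ccdc66 at -1.87 ± 0.52, Pogk at -1.86 ± 0.87, Gnai1 at -1.84 ± 0.01 and Thbs1 at -1.76 ± 0.47. Ribosomal protein genes had a median of 1.13, with 43 higher over all genes and adjusted over the list alone, and oxidative phosphorylation genes of 0.89, with 52 higher, or 53 adjusted over the list alone. Immediate early genes had a median of -0.01 and a mean of -0.13, with 3 higher and 3 lower, or 2 and 3 adjusted over the list alone. After centring the counts were 36 and 0, 34 and 1, and for immediate early genes 0 and 8, with a median of -0.40. The camera adjusted p was 3.52e-08, 2.16e-06 and 0.0254 for these lists, or 6.74e-14, 6.85e-09 and 0.0125 after centring, and an adjusted p = 0.827 with an estimated correlation for each. The immediate early call was lost without siSelT-5 replicate 1 (adjusted p = 0.0712) and with a value required on 1 array of each group (0.0578), and the ribosomal and oxidative phosphorylation calls with genes of several probes alone (0.0859 for each).

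For siSelT-5 2563 genes passed, 2264 higher and 299 lower (88.3% higher), and after centring 1864, 915 higher and 949 lower (49.1%). The 12 named genes passed on both scales, and without siSelT-1 replicate 1 or siSelT-1 replicate 2 the count was 1623 in each case. The larger count than for siSelT-1 depended on the processing. From each construct's arrays alone 1623 genes passed against 2089 for siSelT-1, and with a common spread 1460 against 1588. With array weights siSelT-5 kept the larger count, 2016 against 1920. The upward shift followed the probes. Values on both siSelT-5 arrays and on neither siSelT-1 array were found for 7460 probes, unnamed ones included. Those of them with a single gene name had a median of -0.61, against 0.38 for probes of a single gene name measured on all arrays.

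**Figure D4:**
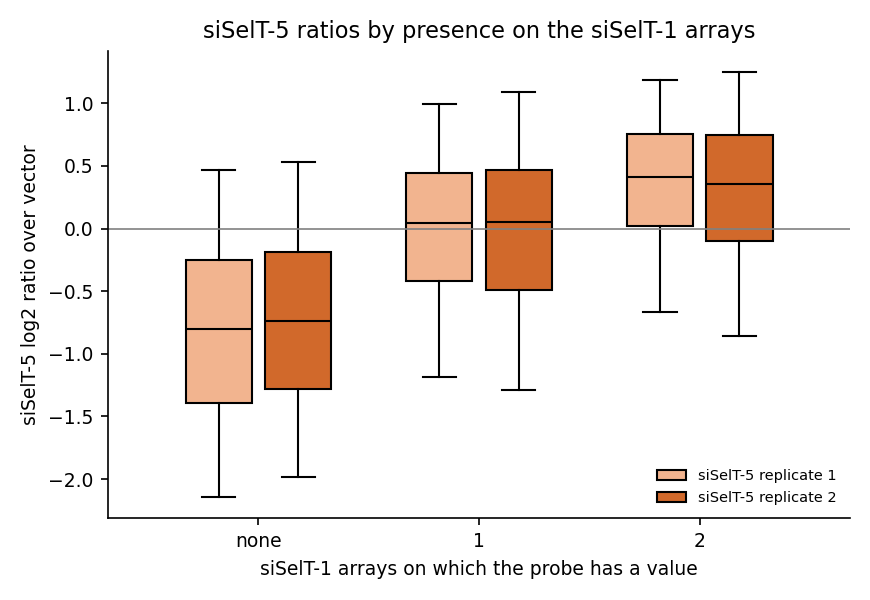
Log2 ratio over vector (y axis) on each siSelT-5 array for probes with a value on 0, 1 or 2 of the siSelT-1 arrays; boxes span the quartiles, lines mark medians and whiskers reach from the 5th to the 95th percentile. Unnamed probes are included. On siSelT-5 replicates 1 and 2 the medians are -0.80 and -0.74 for probes with a value on neither siSelT-1 array. For probes with a value on both siSelT-1 arrays they are 0.41 and 0.36.

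siSelT-1 minus siSelT-5 asks whether the constructs differed. Igf2 stood at -1.53 ± 0.15 with siSelT-1 and 1.01 ± 0.07 with siSelT-5 (SD, n = 2), a difference of -2.55. Postn, the matrix protein periostin, stood at -0.78 ± 0.05 and 1.64 ± 0.12, a difference of -2.42 that both of its probes shared in sign. Speer4b stood at 1.77 ± 0.03 and -0.11 ± 0.05, a difference of 1.87. These were the 3 genes that passed, as deposited (adjusted p = 0.0219, 0.0219 and 0.0440) and centred. With the replicate number as a block none of them did (adjusted p = 0.0819 for each), and Speer4b did not with a value required on 1 array of each group (0.0586). Tmem242 (-1.79), A630052E07Rik (-1.94), Rrp1 (-1.63), Mcm4 (-1.40), Arpp19 (1.57), Six5 (1.46), Bcl7a (1.25), Gnai1 (1.11) and Gm2a, which lay between Arpp19 and Six5, came next and did not pass (largest adjusted p = 0.0543). A further Mcm4 probe had values on the siSelT-5 arrays alone, at -0.66 and -0.03, opposite to the tested probe. Ribosomal protein, oxidative phosphorylation and cell cycle genes stood lower with siSelT-1 relative to other genes, with median differences of -0.62, -0.51 and -0.57 and camera adjusted p of 1.20e-05, 1.24e-05 and 0.0272, or 6.37e-07, 2.11e-06 and 0.00974 after centring. With an estimated correlation, on 2 residual degrees of freedom, the adjusted p was 0.913 for each list, which cannot decide these calls. No member passed over all genes, against 31, 30 and 6 lower adjusted over the list alone.

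Of all genes 1697 had an unadjusted p under 0.05 for the difference. The count of 3 depended on the processing: 2512 genes passed with arrays centred on all values (39 higher and 2473 lower), 279 with array weights and 15 with a common spread. limma called 0 genes without siSelT-1 replicate 1 and 0 without siSelT-1 replicate 2 (628 and 512 at an unadjusted p under 0.05), 1796 without siSelT-5 replicate 1 and 1789 without siSelT-5 replicate 2. The cell cycle call was lost without siSelT-5 replicate 2 (adjusted p = 0.0775) and with arrays centred on all values (0.0803). The ribosomal call was lost with a common spread, where the median difference was -0.11 (0.257), and with genes of several probes alone (0.668), as was the oxidative phosphorylation call (0.145).

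The constructs shared 18 genes that passed and moved at least 2-fold on every array of each, 15 up and 3 down. The 15 included Cbr3, Ets2, Hmgn1, Gstm1, Sod1 and Jup, and the 3 were Thbs1, Rtca and Nupr1. Independent lists would share 1.69 and 0.0757, and simulated unchanged groups with a common vector culture shared 0.64 and 0.54 on average. Neither number includes a gene-specific dye effect, which all 4 arrays would share. Both also treat genes as independent, although Cbr3, Ets2, Hmgn1 and Pigp among the 15 are neighbours on chromosome 16. Centred on shared probes the constructs shared 10 genes, 4 up and 6 down, and centred on all values 15, 14 up and 1 down. Across genes, which are not independent, Pearson's r between the construct means was 0.552, Spearman's rho 0.562 and the share of equal sign 72.1%. Simulated unchanged groups that share a vector culture gave 0.682, 0.657 and 74.0%, which these measures did not exceed, while the covariance of 0.105 exceeded the simulated 0.0487. The simulation assumed 1 vector culture behind all 4 arrays that varied like a knockdown culture, and this assumption sets its correlation. A control shared in this way could give such agreement without any effect. Whether the arrays shared vector RNA is not stated, so the simulation cannot show how much a common control gave here.

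Several of the highest genes were neighbours on chromosome 16. Of 10 tested genes in order from Cbr3 to Hmgn1, Cbr3, Dop1b, Pigp (1.14), Ets2, Psmg1 (1.03) and Hmgn1 exceeded 1.00 for both constructs together, and Vps26c (0.61), Ttc3 (0.44) and Dyrk1a (0.38) rose as well. Morc3 (-0.10) did not pass. After subtraction of the array medians, the window had a median of 1.06 with siSelT-1 (95% interval 0.51 to 1.47, 10 genes) and 0.46 with siSelT-5 (-0.03 to 0.87). The window was chosen because it stood highest for siSelT-1, so the siSelT-1 interval is not a test against 0.

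**Figure D5:**
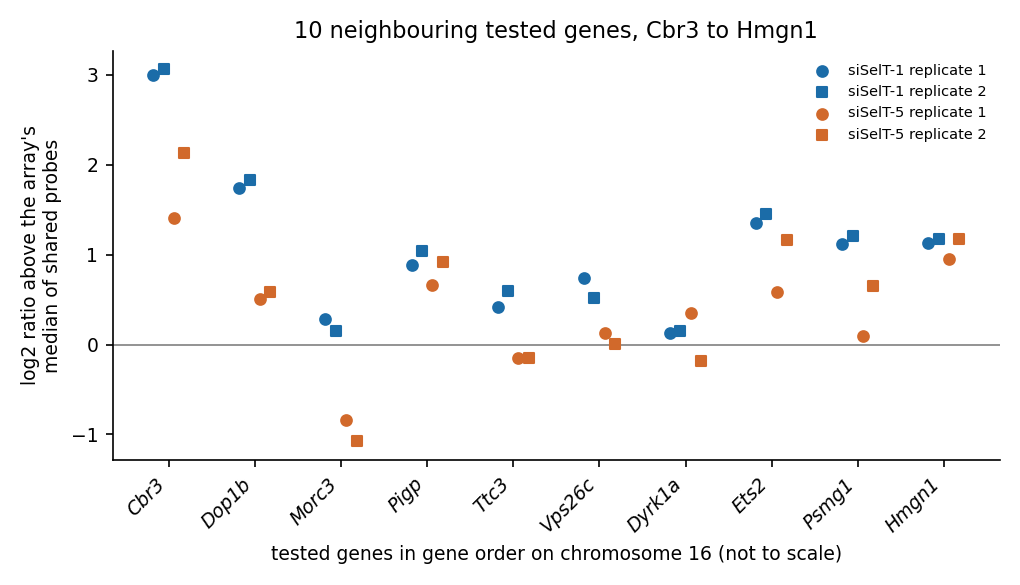
Log2 ratio above the median of shared probes of each array (y axis) for 10 tested genes in their order on chromosome 16 (x axis, not to scale), with points for the 4 arrays. With siSelT-1 10 of 10 gene means lie above 0, and with siSelT-5 8 of 10.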

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

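Both tests of the siSelT-5 shift and the alternative with genes of several probes were chosen after the values were seen. The tests of the ribosomal and oxidative phosphorylation genes were written before their results, that on the siSelT-1 arrays after the other values were seen. Igf2, Postn and Speer4b stood out because the difference between the constructs passed the test, with siSelT-1 minus siSelT-5 at -2.55, -2.42 and 1.87 log2. With either siSelT-1 array left out limma called 0 genes for this difference (628 and 512 at an unadjusted p under 0.05), and with the replicate number as a block none of the 3 passed (adjusted p = 0.0819 for each). The cell cycle, oxidative phosphorylation and ribosomal protein lists stood out for the same reason, with median differences of -0.57, -0.51 and -0.62. With an estimated correlation camera's adjusted p was 0.913 for each, a test on 2 residual degrees of freedom that cannot decide these calls. The cell cycle call was lost without siSelT-5 replicate 2 (adjusted p = 0.0775) and with arrays centred on all their values (0.0803). Among probes without a gene name, which entered none of the main comparisons, 10 of 730 stood at least 2-fold above vector on all 4 arrays (1.37%), at ratios of 1.03 to 2.20, against 17 of 6251 named probes (0.272%; Fisher's exact test, two-sided, p = 0.000236).

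The siSelT-5 ratios of genes measured on all arrays lay above 0, with a shift of 0.39. The dimmer probes of the same genes argue against higher transcript levels alone, which would raise every probe of a gene: where shared probes averaged above 0, the dimmer probes of 490 genes had a median of -0.48 (95% interval -0.55 to -0.42; all dimmer probes -0.61). A candidate explanation is a ratio that depends on probe brightness, since shared probes exceeded dimmer probes of the same gene by a median of 0.74 (0.66 to 0.81; 736 genes, 83.2% of them in this direction). Among 11 genes tiled with many probes, 11 of 11 had this direction, with a median of 1.23. What stays open is the brightness itself, read here from missing values on the siSelT-1 arrays since no intensities were used, and whether dimmer probes measured their transcripts as well, so a rise seen by the shared probes beside a bias of the dimmer ones is not excluded.

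Ribosomal protein and oxidative phosphorylation genes stood above other genes with both constructs, and more so with siSelT-5, though with an estimated correlation no call held (adjusted p = 0.757 for siSelT-1, 0.827 for siSelT-5 and 0.913 for the difference). Their dimmer probes on the siSelT-5 arrays stood at -0.18 against all dimmer probes (-0.23 to 0.16, 23 probes), so a dependence on brightness may account for their siSelT-5 ratios. Taken apart, the values were 0.25 for ribosomal protein genes (-0.23 to 0.42, 7 probes of 6 genes) and -0.22 for oxidative phosphorylation genes (-0.60 to 0.03, 16 probes of 9 genes). Probes rather than genes were resampled, so several probes of a gene were taken as independent and the intervals may be too narrow. Genes with 9 or more probes, such as Rpl13a, were kept here but set apart in the test of the siSelT-5 shift. With arrays scaled to a common spread the difference between the constructs for ribosomal protein genes was -0.11 (adjusted p = 0.257, against 1.20e-05 as deposited). On the siSelT-1 arrays, 34 probes of 22 of these genes with a value on a single array stood 0.55 above all such probes (0.09 to 0.76), where a dependence on brightness predicted no excess. Probes may still differ in brightness within that class. On siSelT-1 replicate 1 its median, 0.26, even lay above that of shared probes, 0.19. The test therefore cannot exclude brightness there, while an effect of the knockdown stays open and was not tested separately.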

How the results depend on the processing

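Centring on shared probes, unnamed probes kept, genes with 2 or more probes, and the fit without the siSelT-5 arrays were chosen after seeing the data. Of the main counts and correlations recomputed, 93 stayed within their limits and 46 moved; of the single genes and lists, 1103 kept their direction and side of the threshold, 134 no longer passed, 47 newly passed and 2 reversed. The reversals were Txnrd3 at -0.014 with arrays centred on shared probes and Gpx1 at -0.054 without the siSelT-5 arrays. Of 61 named calls, 61 held with arrays centred on all values, 56 centred on shared probes, 57 with a common spread, 12 without siSelT-1 replicate 1, 37 without siSelT-1 replicate 2 and 61 without either siSelT-5 array.

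For siSelT-1 the count of 650 became 324 centred on all values, 423 centred on shared probes, 1588 with a common spread, 67 with a value required on 1 array of each group, 1920 with array weights, 35 with a replicate block, 1248 at adjusted p 0.10, 52 at 2-fold, 2089 from its arrays alone and 231 with genes of 2 or more probes. For siSelT-5 the count of 2563 became 1460 with a common spread, 1623 from its arrays alone, 516 at 2-fold and 584 with genes of 2 or more probes. For both constructs 2554 became 106 at 2-fold, 1615 with a single mean over the 4 arrays and 560 with genes of 2 or more probes. The direction at 2-fold turned once arrays were centred on shared probes. For both constructs 90 higher and 16 lower became 16 and 59. For siSelT-5 449 and 67 became 65 and 199, and for siSelT-1 37 and 15 became 23 and 33. For the difference 3 became 2512 centred on all values (39 higher, 2473 lower), 15 with a common spread, 279 with array weights, 0 in limma with the block (1674 at an unadjusted p under 0.05), 1310 at adjusted p 0.10 and 298 with genes of 2 or more probes. The causes of these moves were not tested.

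Leave-one-out counts ranged from 0 to 3190 for both constructs, 0 to 2089 for siSelT-1, 1623 to 3027 for siSelT-5 and 0 to 1796 for the difference; the 0 counts, all from limma, came without a siSelT-1 array, with 1846 at an unadjusted p under 0.05 for both constructs, 390 and 585 for siSelT-1 and 628 and 512 for the difference. A lone array was assumed to vary like the other group. Without a siSelT-1 array the spread thus came from the siSelT-5 arrays alone, which varied more (root mean square SD 0.349 against 0.164). Counts without a siSelT-1 array and without a siSelT-5 array therefore rest on unlike spreads. For siSelT-5 the fits without a siSelT-1 array gave the count of its own arrays alone and are no separate check. Lists called ranged from 3 to 3, 5 to 7, 2 to 3 and 2 to 4. With the estimated correlation camera called 0, 0, 0 and 0 lists (0 at an unadjusted p under 0.05; smallest adjusted p 0.757), and that estimate, from -0.04 to 0.78 over lists, rests on 2 residual degrees of freedom. So do the p-values of that test. For unfolded protein response genes, with an estimate of -0.04, camera's unadjusted p for the difference went from 0.0171 to 0.121. The counts of 0 therefore cannot tell whether correlation accounts for the lost calls. With genes of 2 or more probes camera called 0, 0, 1 and 0 of 12 lists (3, 2, 3 and 3 at an unadjusted p under 0.05), and without the siSelT-5 arrays 5 for both constructs. The 18 genes shared by the constructs became 15 centred on all values, 10 centred on shared probes and 173 at 1.5-fold. The alternatives for the targeted gene were not run. Signal over background is not part of the ratios and was not used here.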

Other observations

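Histone genes and the lists of dimmer probes named below were chosen after their values were seen. So were the tests of chance placement and of copy number on chromosome 16 below, while the test of dimmer probes there was written before its result. Clustered histone genes stood far above vector with siSelT-5: of 21 measured, 16 rose, with a median of 1.31, while with siSelT-1 7 rose, with a median of 0.32. Less the shift of each construct, the medians were 0.92 and 0.18. H2ac10 stood at 1.59 and H2bc22 at 1.52 with siSelT-5, against 0.64 and 0.15 with siSelT-1. The H3 and H4 genes among the 21, H4c14 (-1.26), H3c13 (-0.43), H3c2 (-0.12), H3c6 (0.24) and H4c1 (0.29), did not pass with siSelT-5. Most mRNAs of these genes lack a poly(A) tail, and the cDNA was primed with oligo-dT. Along the chromosomes, the highest window of 10 tested neighbours for siSelT-5 ran from H2bc15 to H2ac7 on chromosome 13, at 0.99 above all genes, and the lowest for siSelT-1 minus siSelT-5 from Zkscan3 to H2ac10, at -0.67 (permutation p = 0.005 for each, the smallest that 199 random orders can give).

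Dimmer probes of the siSelT-5 arrays, which entered none of the main comparisons, covered more genes of some lists than the main measurement. Those of cell cycle genes stood 0.60 above all dimmer probes (95% interval 0.28 to 0.78; 47 probes), and those of immediate early genes stood lower, at -0.37 (-0.59 to -0.10; 15 probes). These were the 2 of 24 lists whose interval left out 0, with no adjustment over lists, and the intervals of the other 22 included it.

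Of all windows of 10 tested neighbours, that from Cbr3 to Hmgn1 on chromosome 16 stood highest for both constructs together, at 0.84 above all genes, and for siSelT-1 alone, at 1.06. Chance placement gave at most 0.64 and 0.58 in 199 random gene orders (permutation p = 0.005, the smallest they can give), a test first run with siSelT-1 and 100 orders. A dependence on brightness cannot be told apart here: the 5 dimmer probes stood at 0.11 against all dimmer probes (-0.08 to 0.15), an interval that includes 0 as brightness predicts, but they belong to only 2 genes, and the need for at least 5 genes was set after this value was seen. A gain of copies in both knockdown cultures may be considered beside a loss in the vector cells, yet these cannot be told apart: the lower of the construct medians was 0.46 for siSelT-5 (-0.03 to 0.87), the interval includes 0, and the bound first written, which it meets and which would have excluded a gain shared by both, was replaced after the result because an interval that includes 0 does not show absence. Copy number was not measured, and an effect of the knockdown on these genes stays open and untested.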
